A study of Mus musculus with 2 samples.

How the data were processed

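RNA was measured in single cells of the lateral ganglionic eminence (LGE) of mouse embryos at E12.5, in 2 samples of 1 group, called replicates 1 and 2 by the number in their labels. Per the labels, cells were encapsulated with the 10x Chromium system and the 3' ends of the cDNA were prepared with a modified Nextera XT protocol. The deposited values are counts of unique molecular identifiers (UMIs) per gene and barcode, not normalized. They were made with Cell Ranger 3.0.2 against mm10, per the submitters' processing notes, and the matrix header names the same version of the software. Each matrix lists all 6794880 barcodes, before any selection of cells, and 28692 genes. The annotation behind the counts, and whether counting used strand, were not given in the sources used here. Gene positions came from GENCODE vM21 (GRCm38, the assembly of mm10), matched by gene ID: 28339 IDs had a match and 27194 of these had an equal symbol. Genes whose exons overlap those of another gene on the opposite strand are therefore uncertain, since UMIs of both could be counted for either.

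Cells were called per library as barcodes with at least 0.1 of the 99th percentile of the UMI totals of the 3000 deepest barcodes, which gave minimums of 3773 UMIs in replicate 1 and 4013 in replicate 2. At least 1000 detected genes and under 10% of UMIs from mitochondrial genes were required, which left 12678 and 14491 barcodes. Doublets were scored per library with Scrublet (in scanpy 1.11.5), and the top-scoring cells were removed at 0.8% per 1000 cells, 1286 and 1680 cells. Scrublet's own threshold would have marked 615 (4.85%) and 859 (5.93%). This left 11392 and 12811 cells with medians of 8598 and 8458 UMIs. Both libraries were clustered together without integration (counts per 10000, log1p, 2000 variable genes with the library as batch, 30 principal components, 15 neighbours, Leiden at resolution 1.0). All 147 genes of the readout lists, Gsx2, Ascl1 and Gsx1 among them, were held out of the variable genes.

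Clusters were named from marker lists of 14 cell classes, using the fold of a cluster's pooled counts per 1e6 UMIs (CPM, computed here from the deposited counts) over all other cells with a pseudocount of 10 CPM. A name needed at least 3 markers with a fold of 1.5 or more and the highest mean log2 fold of the class list. A progenitor name was refused where at least 3 of 4 pan-neuronal genes (Tubb3, Dcx, Stmn2, Mapt) had such a fold. A cluster stayed unnamed where its top 10 genes held more markers of another class than of its own. A cluster named GABAergic took the striatal or MGE (medial ganglionic eminence) name where its top 10 genes held more of those markers. This scoring rule, unlike the markers, was set after the clusters had been seen. So was a split of the progenitor clusters into those with under 50 CPM of Nkx2-1 and under 20 CPM of Fgf17 (low Nkx2-1, 2638 and 3125 cells) and the rest. Nkx2-1 is a transcription factor of the MGE and preoptic area.

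To compare cells at 1 depth, each cell was thinned to 6200 UMIs without replacement (seed 1). That depth was the 10th percentile of the progenitor-like cells, rounded down to a whole 100, and 618 and 656 shallower progenitor-like cells were left out. The 5388 and 6173 remaining cells fell into 4 detection classes by whether at least 1 UMI of Gsx2 and of Ascl1 was found. Thinned counts were summed per library and class. The 8 sums were fitted with edgeR 4.0.16 (R 4.3.3; TMM, filterByExpr, robust quasi-likelihood test) with the library as a block, because the 4 classes are parts of the same libraries. Their library differences went together: across 8792 genes with at least 10 counts, the correlation between classes was 0.458 to 0.788 over the 6 pairs of classes. The fit tested 12161 genes with 3 residual degrees of freedom, and adjusted p is Benjamini-Hochberg over all genes tested, without Gsx2 and Ascl1, with 0.05 as the threshold. A second fit compared stages on 6 sums of all UMIs (VZ progenitor-like, SVZ progenitor-like, and GABAergic or striatal neuron-like cells; 13743 genes, 2 residual degrees of freedom), and only held-out readout genes are reported from it.

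The gene lists, markers, tests, the rule for named genes and a first set of alternative settings were fixed before the data were examined. The readout lists were Gsx and Ascl1, Notch ligands and modulators, Notch receptors and effectors, Id genes, bHLH partners and Olig, cell cycle exit, S phase, G2 and M phase, and dissociation and stress response. Further lists for the detection classes were radial glia, LGE transcription factors, neuronal differentiation, dorsal LGE and pallial boundary, MGE and Shh response, and 2 lists of other cell types (pallial lineage; vascular, blood and immune). The radial glia list holds the same 12 genes as the VZ markers. Dlx1, Dlx2, Arx and Sp9 were both SVZ markers and LGE transcription factors. Calls of these lists are thus not independent of the cluster naming where classes differ in their SVZ share. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. Named genes were the 12 with the largest fold change in each direction among those past the threshold, with a mean of at least 20 CPM and the same sign in both libraries, plus up to 4 members of each list with the smallest p. In the stage comparisons they were list members alone, with Gsx2, Ascl1 and Gsx1. Which of these the text spells out was chosen after their values were seen. For the genes of largest fold change the agreement of the libraries follows from this rule. For the others it follows in large part from passing the threshold in a fit of these 2 libraries. Of the other named genes, 44 of 56 passed the threshold between Gsx2+Ascl1+ and Gsx2+Ascl1- cells, 31 of 56 between Gsx2+Ascl1+ and Gsx2-Ascl1+, 25 of 55 between Gsx2+Ascl1- and Gsx2-Ascl1-, 48 of 56 between the single-positive classes, 35 of 35 between SVZ and VZ and 34 of 35 between neurons and SVZ, and all that passed had the same direction in both libraries.

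Both fits were tested on simulated counts with 200 genes changed by known folds, 50 of each size. At a 2-fold change, 64% of genes were recovered in the Gsx2+Ascl1+ against Gsx2+Ascl1- comparison (11980 genes), with 4 of 94 calls false. The recovered share was 88% for Gsx2+Ascl1+ against Gsx2-Ascl1+ (11973 genes; 14 of 157 calls false), 64% for Gsx2+Ascl1- against Gsx2-Ascl1- (11969 genes; 5 of 100 false) and 84% for the single-positive classes (11970 genes; 3 of 118 false). It was 90% for SVZ against VZ (13453 genes; 13 of 171 false) and 86% for neurons against SVZ (13457 genes; 20 of 157 false, 12.7%). At a 1.25-fold change the shares lay between 12% and 48%.

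Odds ratios carry exact conditional 95% intervals and shares exact binomial ones; both cover counting error alone. The share that a count of 0 allows is given as 3 counts of the total. The correlation of the summed libraries was taken on log2(CPM + 1). Nothing in the labels says that the samples came from separate embryos. The library block takes out the level difference between the samples. So p-values measure only how far the differences between classes or stages varied between these 2 samples, a spread that may be technical. The chi-square per degree of freedom between the libraries was 169 over 15872 genes (139 without the erythroid cells), against 2.10 between random parts of replicate 2, so they are not copies of 1 library.

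Alternatives tried were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no low-count filter, no replicate block, each replicate left out, no thinning, thinning to 3100 UMIs, another seed, VZ cells alone, sums split by cluster with cluster as covariate, the UMI minimum multiplied by 2, no doublet removal, a mitochondrial maximum of 5% and resolution 0.5. Added after the data had been seen were the low Nkx2-1 clusters (all, their VZ part, and with cluster as covariate), the remaining progenitor clusters, the phase and detection alternatives, and list counts under every setting. Sums of few cells were left out of the fits with cluster as covariate, which kept 86 sums, or 41 within low Nkx2-1 clusters. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.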

Results

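Single-cell RNA was profiled from the lateral ganglionic eminence (LGE), the part of the embryonic ventral forebrain that makes striatal projection neurons and olfactory bulb interneurons, of mice at E12.5. The series title concerns Gsx2 and Ascl1, which are transcription factors of LGE progenitors, and the balance of progenitor expansion against neurogenesis. There were 2 samples, replicates 1 and 2, of 1 group with no treatment or mutant, so every comparison is between cells of these samples. The deposited matrices held 143951499 UMIs in replicate 1 and 163362216 in replicate 2. Of these, 107483163 and 119618179 lay in the 11392 and 12811 called cells, at medians of 2975 and 3049 genes and 5.32% and 3.81% mitochondrial UMIs per cell. Summed over cells, the libraries had a Pearson correlation of 0.995 and a Spearman correlation of 0.994 across 15872 genes, which are not independent replicates. They still differed beyond counting noise: embryonic globin Hba-x stood at 552 CPM (counts per 1e6 UMIs) in replicate 1 and 17.9 in replicate 2, and Mt3 at 132 and 297. Values below are means ± SD over the 2 replicates unless stated.

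Ventricular zone (VZ) progenitor-like cells, which carried the radial glia genes Fabp7, Slc1a3 and Nes, made up 32.9% ± 1.63 of cells (n = 2), and subventricular zone (SVZ) progenitor-like cells with Dlx1, Dlx2 and Insm1 made up 20.1% ± 2.04. GABAergic neuron-like cells were 11.6% ± 0.503 and striatal projection neuron-like cells, with Ebf1 and Tac1, 8.14% ± 0.751. Of the 3 GABAergic clusters, which enter the neuron stage below, c21 (730 cells; Nkx2-1 318 and Lhx8 632 CPM) and c18 (905 cells; 150 and 181 CPM, led by Gnrh1) carried MGE factors. In c16 (1167 cells) these stood at 10.96 and 8.34 CPM. MGE-derived neuron-like cells, led by Sst and Npy in 1 cluster and Lhx8 and Gbx1 in another, were 15.1% ± 0.104. The series describes LGE cells, while the sample titles say "VT", which the labels do not explain, so the labels do not settle whether tissue beyond the LGE was taken. Glutamatergic neuron-like cells (Neurod6, Tbr1) were 4.03% ± 1.39, at 5.01% in replicate 1 and 3.05% in replicate 2. Cajal-Retzius-like cells were 1.36% ± 0.0189, endothelial-like cells 0.359% ± 0.0882 and microglia-like cells 0.135% ± 0.0579. Another 6.09% ± 0.237 stayed unnamed. All 40 erythroid-like cells were in replicate 1, and 0 of 12811 cells in replicate 2 allows a share of up to 0.0234% at this clustering. No cluster was named pallial progenitor-like, choroid plexus-like, oligodendrocyte precursor-like or pericyte-like. These names and shares depend on the settings: without doublet removal erythroid-like cells were 0.338% of replicate 2, pallial progenitor-like cells 0.868% and 0.580% and pericyte-like cells 0.355% and 0.359% of replicates 1 and 2. At resolution 0.5 no cluster was named GABAergic neuron-like and striatal projection neuron-like cells were 15.6% and 17.4%. MGE-derived neuron-like cells were 22.4% and 22.4% there, 4.76% and 9.02% with a mitochondrial maximum of 5%, and 10.6% and 6.29% with the UMI minimum multiplied by 2. Of the 12 progenitor clusters, 6 had low Nkx2-1, the transcription factor of the neighbouring MGE, and 6 had high Nkx2-1, a split made after the data had been seen. Nkx2-1 stood at 8.18 to 19.8 CPM in the former and at 250 to 833 CPM in the latter. The high Nkx2-1 clusters held 3368 of 6006 and 3704 of 6829 progenitor-like cells in replicates 1 and 2. By this marker the progenitor-like cells, which the class comparisons pool, were not of LGE type alone.

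Gsx2, a homeodomain factor of LGE progenitors (ENSMUSG00000035946; chromosome 5, 75075601 to 75077893, + strand, 4 exons, mm10), was found in progenitors and scarcely in neurons. After thinning every cell to 6200 UMIs, 22.1% ± 4.57 of VZ and 22.9% ± 4.43 of SVZ progenitor-like cells had a Gsx2 UMI (n = 2), against 3.41% of GABAergic, 1.36% of striatal, 2.73% of MGE-derived and 0.29% of glutamatergic neuron-like cells. Ascl1, a proneural bHLH factor (ENSMUSG00000020052; chromosome 10, 87490819 to 87493660, − strand, 2 exons), was found in 54.7% ± 6.14 of VZ and 87.9% ± 1.85 of SVZ cells, in 36.7% of MGE-derived, 21.8% of GABAergic, 10.6% of glutamatergic and 9.83% of striatal cells. In endothelial-like cells, which should lack both genes, 0 of 45 and 0 of 37 thinned cells had Gsx2, which allows shares of up to 6.67% and 8.11%, and 2.22% and 5.41% had Ascl1. The neuronal Gsx2 shares lie under that limit, which rests on few cells. They are thus not told apart from background by share. By level, GABAergic cluster c16 (7.92 and 17.6 CPM) and MGE-derived cluster c13 (5.85 and 11.7 CPM) stood above the highest Gsx2 level of endothelial-like, microglia-like or erythroid-like cells (3.02 CPM). Without thinning, Gsx2 was found in 31.3% ± 5.08 of VZ and 30.3% ± 5.12 of SVZ cells and Ascl1 in 64.6% ± 6.15 and 89.0% ± 1.90, at medians of 10162 and 10067 UMIs in VZ and 9135 and 9285.5 in SVZ cells. Unthinned endothelial-like cells, at medians of 20587 and 24389.5 UMIs, had Gsx2 in 0% and 2.63% and Ascl1 in 4.17% and 15.8%. Ascl1 was highest in the low Nkx2-1 SVZ clusters c20 (1101 ± 129 CPM) and c24 (1033 ± 38.5 CPM), where Gsx2 stood at 76.5 ± 20.2 and 83.6 ± 21.8 CPM. Gsx1, the paralog of Gsx2 (ENSMUSG00000053129; chromosome 5, 147188696 to 147190947, + strand, 2 exons), stood at 30.04 ± 3.57 CPM in the high Nkx2-1 VZ cluster c6, its highest level in a named cluster, and at 118 ± 13.7 CPM in the unnamed cluster c9.

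**Figure D1:**
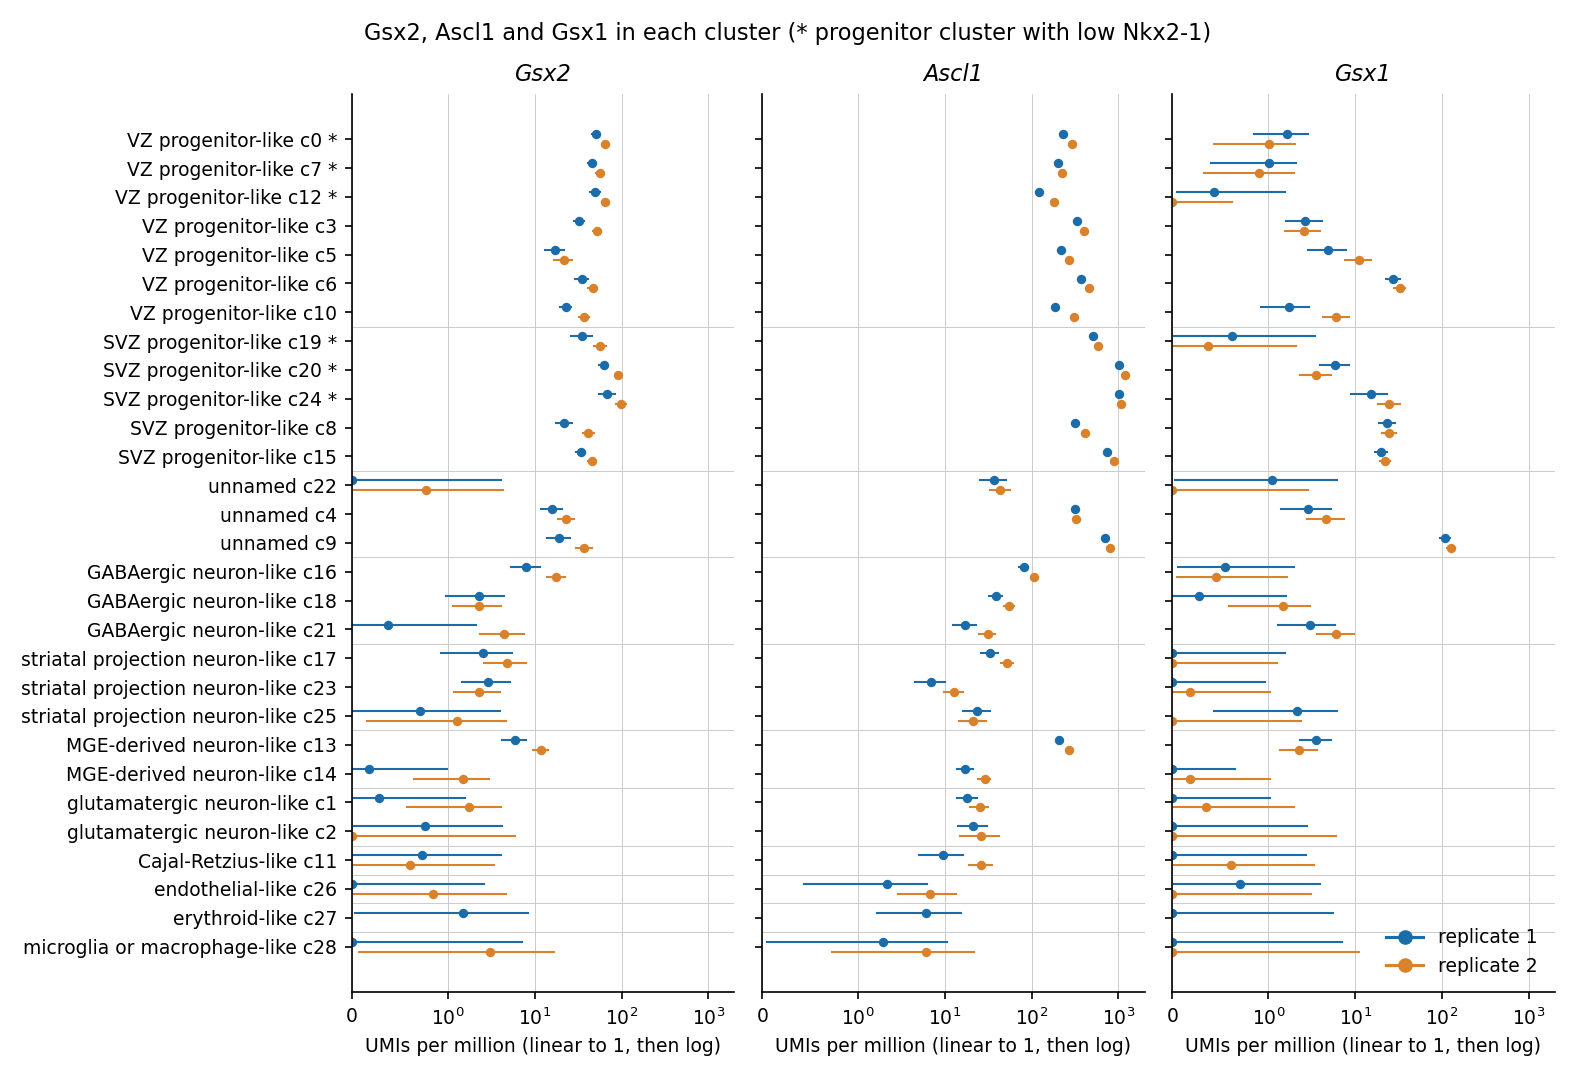
Levels of Gsx2, Ascl1 and Gsx1 in CPM (horizontal axis, logarithmic above 1 and linear below) in each cluster (vertical axis), with 1 point per replicate and exact 95% Poisson intervals for counting error; an asterisk marks progenitor clusters with low Nkx2-1. Ascl1 stood at 1101 CPM in SVZ cluster c20 and 1033 CPM in c24, and Gsx2 at 76.5 and 83.6 CPM in the same clusters.

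The stage comparison asks which regulators change from VZ to SVZ progenitor-like cells and on to GABAergic or striatal neuron-like cells, using genes held out of the clustering. Ascl1 was 1.60 ± 0.04 (SE) log2 units higher in SVZ than in VZ and fell by 4.31 ± 0.05 on the log2 scale in neurons, from 270 ± 41.8 through 814 ± 86.1 to 41.1 ± 8.23 CPM (n = 2). Gsx2 rose much less, by 0.26 ± 0.06 from 43.7 ± 8.77 to 52.6 ± 14.2 CPM, and stood at 4.42 ± 1.71 CPM in neurons. Gsx1 rose from 5.69 ± 1.38 to 15.9 ± 0.225 CPM. The Notch target Hes1, which represses proneural genes, stood at 178 ± 3.47 CPM in VZ and 9.23 ± 1.59 CPM in SVZ cells, a log2 fold change of −4.25 ± 0.07. The Notch ligand Dll1 (uncertain, since an antisense gene overlaps it) was 1.67 ± 0.05 higher and Gadd45g, which restrains the cell cycle, 2.38 ± 0.05 higher in SVZ cells.

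Of 143 readout genes tested between SVZ and VZ, 85 rose and 39 fell at an adjusted p under the threshold in edgeR's quasi-likelihood test, and from SVZ to neurons 10 rose and 128 fell. All 3 Gsx and Ascl1 genes rose into SVZ and fell into neurons, and the camera calls were lost with an estimated correlation (adjusted p = 0.227 and adjusted p = 0.117). Of 10 Notch ligands and modulators, 4 rose into SVZ and 2 fell (adjusted over the list alone, also 4 and 2): Mfng, a Fringe enzyme that modifies Notch, rose from 86.3 to 274 CPM and Hes6 from 164 to 475, while Lfng, another Fringe, had a log2 fold change of −2.18 ± 0.08. The camera call was lost (adjusted p = 0.434 with an estimated correlation). Of 9 Notch receptors and effectors, 8 fell and 1 rose, Nrarp (uncertain, antisense overlap) from 121 to 30.2 CPM and Hey1 from 44.4 to 10.3 CPM (adjusted p = 0.172 with an estimated correlation). All 4 Id genes, inhibitors of bHLH factors, fell into SVZ (adjusted p = 0.172), and Id4 (uncertain, antisense overlap) then rose by 2.20 ± 0.07 in neurons, where 1 Id gene rose and 2 fell. Of 9 cell cycle exit genes, 8 rose into SVZ, with Btg1 at 1.10 ± 0.04 and Cdkn2d at 1.31 ± 0.05 (adjusted p = 0.172). In neurons 4 rose and 5 fell, among the latter Btg2 at −2.62 ± 0.05 (adjusted p = 0.190).

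Of 52 G2 and M phase genes, 51 rose into SVZ (Aurka by 0.85 ± 0.04 and Anp32e by 0.65 ± 0.03; adjusted p = 0.267 with an estimated correlation) and all 52 fell into neurons, Cdk1 by 5.46 ± 0.06 (adjusted p = 0.112). Of 42 S phase genes, 11 rose and 20 fell into SVZ (21 adjusted over the list alone), Cdca7 at 1.08 ± 0.04 and Ung at −1.38 ± 0.06, and camera made no call. This order turned in low Nkx2-1 clusters (26 rose and 4 fell), with a mitochondrial maximum of 5% (24 and 4) and with the UMI minimum multiplied by 2 (19 and 9). All 42 fell into neurons, the one list whose call held there with an estimated correlation (adjusted p = 0.0310), though it was lost in low Nkx2-1 clusters (adjusted p = 0.181). Of 5 bHLH partners and Olig genes, 3 rose and 2 fell into SVZ with no camera call, while the mean (−0.16) differed in sign from the median (0.16). Tcf4 was 0.58 ± 0.04 higher and Olig2 stood at −0.79 ± 0.05, the latter with the opposite sign in low Nkx2-1 clusters (0.32). All 5 fell into neurons (adjusted p = 0.156). Of 9 dissociation and stress genes, 4 rose and 3 fell into SVZ and 2 rose and 4 fell into neurons (2 and 3 adjusted over the list alone), Egr1 at 0.84 ± 0.05 and Dusp1 (uncertain, antisense overlap) at 0.80 ± 0.05, with no camera call. Into neurons, 8 of 9 Notch receptors and effectors fell (adjusted p = 0.153), and of the ligands 3 rose and 7 fell (adjusted p = 0.289). With the UMI minimum multiplied by 2 the order of the G2 and M phase list turned (9 rose and 19 fell into SVZ), and Aurka stood at −0.034.

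**Figure D2:**
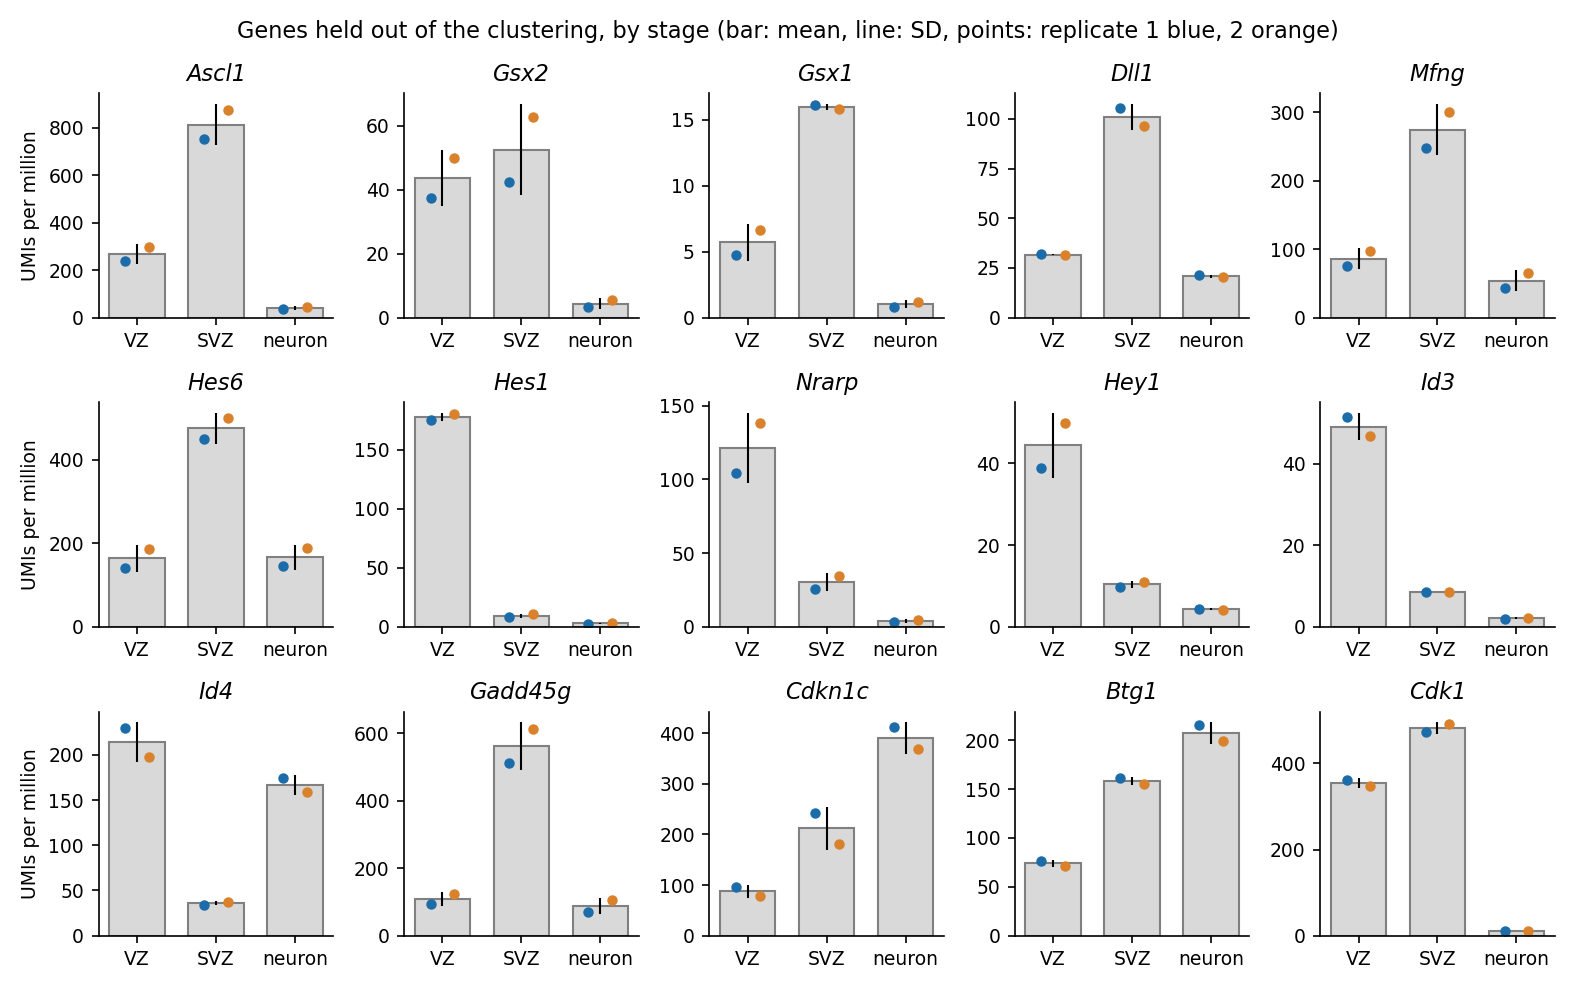
CPM (linear vertical axis, scaled for each gene) of 15 readout genes held out of clustering, in VZ progenitor-like, SVZ progenitor-like and neuron-like cells (GABAergic or striatal). Bars stand at the mean of 2 replicates, with lines for ± SD and 1 point per replicate. Ascl1 goes from 270 CPM in VZ to 814 CPM in SVZ and 41.1 CPM in neurons, while Hes1 goes from 178 to 9.23 and 2.75 CPM.

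The co-detection comparison asks whether Gsx2 and Ascl1 are found in the same progenitors more often than independent detection of the 2 genes would give. In thinned progenitor-like cells Ascl1 was found in 75.5% and 79.2% of cells with Gsx2 against 59.9% and 68.1% of cells without it in replicates 1 and 2. The odds ratio was 2.06 (exact 95% interval 1.76 to 2.41) and 1.77 (1.55 to 2.04), a mean log2 odds ratio of 0.94 ± 0.15 (SD, n = 2). Both genes were found in 17.4% ± 4.10 of progenitor-like cells, Gsx2 without Ascl1 in 5.03% ± 0.447, Ascl1 without Gsx2 in 49.5% ± 1.63 and neither in 28.1% ± 6.18. These classes rest on 781 and 1253, 254 and 330, 2606 and 3128, and 1747 and 1462 cells. A cell without a UMI may still express the gene, so the negative classes hold such cells too. SVZ cells were 46.2% ± 2.15 of Gsx2+Ascl1+ and 49.4% ± 1.48 of Gsx2-Ascl1+ cells, but 9.50% ± 2.85 of Gsx2+Ascl1- and 14.3% ± 1.57 of Gsx2-Ascl1- cells. Cells of low Nkx2-1 clusters were 53.3% ± 0.994, 37.7% ± 1.60, 64.9% ± 3.46 and 50.2% ± 2.34 in the same order.

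The first class comparison asks what Gsx2+ progenitors with Ascl1 express that Gsx2+ progenitors without it do not. In Gsx2+Ascl1+ cells the bHLH-orange repressor gene Helt (ENSMUSG00000047171; chromosome 8, 46292039 to 46294671, − strand) stood at 55.0 and 65.7 CPM against 3.91 and 8.51 CPM in replicates 1 and 2, a log2 fold change of 3.21 ± 0.21 (SE; adjusted p = 4.64e-22, higher in both replicates). Gadd45g (ENSMUSG00000021453; chromosome 13, 51846678 to 51848468, + strand) stood at 476 and 550 against 39.8 and 69.0 CPM (3.19 ± 0.27). The Notch ligand genes Dll3 (ENSMUSG00000003436; chromosome 7, 28293553 to 28302238, − strand) and Dll1 (ENSMUSG00000014773; chromosome 17, 15367354 to 15376872, − strand; uncertain, antisense overlap) were 2.46 ± 0.26 and 2.42 ± 0.13 higher. Gsx2+Ascl1- cells had more of all 12 radial glia genes tested, with Fabp7 (ENSMUSG00000019874; chromosome 10, 57784881 to 57788450, + strand) at −1.58 ± 0.08 and the glutamate transporter gene Slc1a3 (ENSMUSG00000005360; chromosome 15, 8634124 to 8710764, − strand) at −1.44 ± 0.08, and more of Hes1 (ENSMUSG00000022528; chromosome 16, 30064384 to 30067796, + strand), at −1.04 ± 0.08.

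Of 9 Notch ligands and modulators, 5 rose and 1 fell (the same counts adjusted over the list alone), with Hes6 at 1.93 ± 0.07 and Mfng at 1.46 ± 0.09. The camera call held with an estimated correlation (adjusted p = 0.0207). Of 9 Notch receptors and effectors, 1 rose and 6 fell (7 adjusted over the list alone; adjusted p = 0.0231), including Hey1 at −1.22 ± 0.13, Nrarp (uncertain) at −0.76 ± 0.09 and Hes5 at −0.35 ± 0.03. Among Id genes 3 of 4 fell, all 4 adjusted over the list alone (adjusted p = 0.0207): Id3 at −0.98 ± 0.14 and Id4 (uncertain) at −1.60 ± 0.07. All 12 radial glia genes fell (adjusted p = 0.0207), Ptprz1 at −0.86 ± 0.04 and Nes at −0.48 ± 0.04. These 12 genes also named the VZ clusters, as Dlx1, Dlx2, Arx and Sp9 named the SVZ ones. SVZ cells were 46.2% of Gsx2+Ascl1+ and 9.50% of Gsx2+Ascl1- cells, so these changes are not independent of the naming. Of 15 LGE transcription factors, 9 rose (adjusted p = 0.0143), with Dlx2 at 1.57 ± 0.05, Dlx6 at 1.95 ± 0.19 and, with antisense overlap, Dlx1 at 1.95 ± 0.06 and Sp9 at 1.55 ± 0.07. Of 12 neuronal differentiation genes, 8 rose (9 adjusted over the list alone) and 1 fell (adjusted p = 0.0207), Tubb3 at 1.12 ± 0.04 and Elavl3 at 0.86 ± 0.06.

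Of 9 cell cycle exit genes, 6 rose (adjusted p = 0.0444 with an estimated correlation), Btg2 at 1.18 ± 0.08 and Cdkn2d at 0.44 ± 0.10. Cdkn2d turned to −0.24 in VZ cells alone, −0.17 with cluster as covariate, −0.34 in VZ cells of low Nkx2-1 clusters and −0.23 in low Nkx2-1 clusters with that covariate, none past the threshold. Of 52 G2 and M phase genes, 44 rose (49 adjusted over the list alone), Cenpe at 0.66 ± 0.06 and Top2a at 0.51 ± 0.04, and the camera call was lost (adjusted p = 0.165 with an estimated correlation). In VZ cells of low Nkx2-1 clusters 0 rose and 1 fell, with Top2a at −0.067 and Tpx2 at −0.011, neither past the threshold. Of 42 S phase genes, 10 rose and 1 fell (4 adjusted over the list alone) with no camera call, Cdca7 at 0.64 ± 0.06 and Rrm2 at 0.46 ± 0.04. Of 5 bHLH partners and Olig genes, 4 rose (adjusted p = 0.146), Olig2 at 0.51 ± 0.08 and Tcf12 at 0.46 ± 0.07. Gsx1, at 8.19 and 15.8 against 2.61 and 0.946 CPM, rose by 2.96 ± 0.47 on few UMIs, and as the 1 tested member of its list it gave a camera call that was lost (adjusted p = 0.1696). Stress genes gave 1 higher (Egr1, 0.35 ± 0.10) and 1 lower (Jun, uncertain, −0.79 ± 0.05) of 8 with no camera call. Of 8 MGE and Shh response genes, 2 rose (Nkx2-1 at 0.86 ± 0.07, Lhx6 at 1.08 ± 0.22) and 1 fell (Nkx6-2, uncertain, −1.83 ± 0.31), with no camera call. This order turned without the replicate block, with cluster as covariate and in VZ cells of low Nkx2-1 clusters (0 rose and 1 fell in each) and with the UMI minimum multiplied by 2 (2 and 4). Lhx6 stood at −0.16 with cluster as covariate. Of 7 dorsal LGE and pallial boundary genes, 1 rose and 3 fell, Pax6 at −0.66 ± 0.09, with no camera call and a median (0.0069) and mean (−0.019) of opposite sign. None of 4 pallial lineage genes passed (median −0.28, while the mean rests on Eomes, which had 0 UMIs in Gsx2+Ascl1- cells), nor did any of 4 vascular, blood and immune genes (0 rose and 1 fell adjusted over the list alone).

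In all, 1093 genes were higher and 956 lower of 12161 tested (2049; edgeR quasi-likelihood test), and 284 without the replicate block. With cluster as covariate 250 passed of the 7947 tested. Among VZ cells alone 586 genes passed, with 5 of 9 Notch ligands and modulators higher and 9 of 12 radial glia genes lower, while Hes5 turned to 0.13 (adjusted p = 0.0143 in edgeR).

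**Figure D3:**
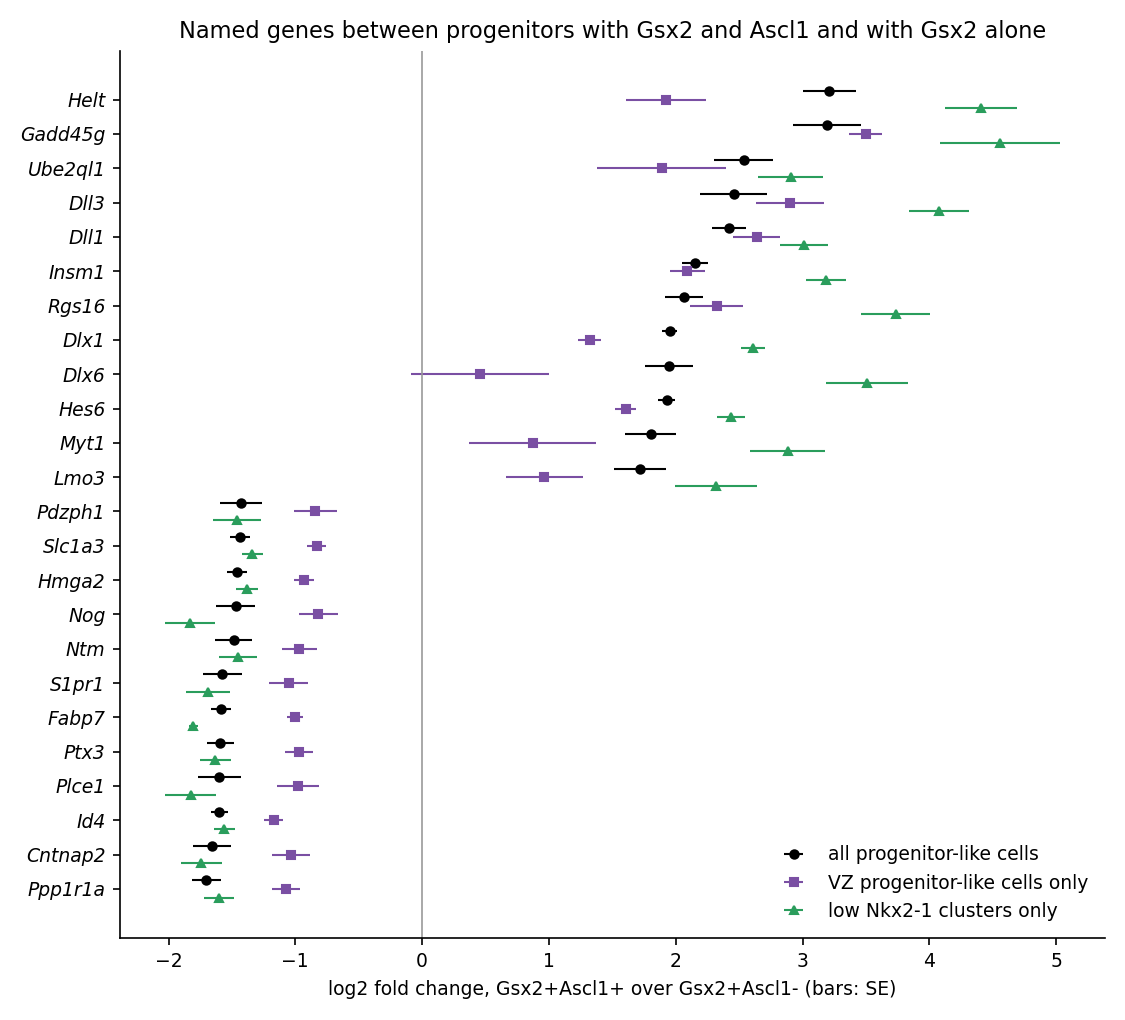
Log2 fold change of Gsx2+Ascl1+ over Gsx2+Ascl1- progenitor-like cells (horizontal axis) for the 24 genes with the largest changes (vertical axis), with points for all progenitor-like cells, VZ cells alone and low Nkx2-1 clusters, and lines for ± SE. Helt stands at 3.21 over all cells, 1.92 in VZ cells and 4.41 in low Nkx2-1 clusters, and Slc1a3 at −1.44, −0.83 and −1.34.

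The second class comparison asks how Gsx2 detection separates Ascl1+ progenitors. Gsx2+Ascl1+ cells had more Helt (1.05 ± 0.08, adjusted p = 1.15e-18, both replicates), more of the neurotrophin receptor gene Ntrk2 (1.02 ± 0.07), Lix1 (0.81 ± 0.05) and Pax6 (0.64 ± 0.07), a homeodomain factor of pallial and dorsal LGE progenitors, than Gsx2-Ascl1+ cells. They had less of the MGE interneuron factor Lhx6 (−1.05 ± 0.09), of the neuronal genes Stmn2 (−0.91 ± 0.05), Gad1 (−0.99 ± 0.13) and Rtn1 (−0.59 ± 0.04), and of St18 (−0.79 ± 0.10). In all 223 genes were higher and 239 lower, 462 of 12161. Of 7947 genes tested with cluster as covariate 59 passed. Shuffling class labels within cluster and library gave 138.8 on average.

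Of 12 neuronal differentiation genes 8 fell (9 adjusted over the list alone; adjusted p = 0.0385 with an estimated correlation), among them Tubb3 at −0.26 ± 0.03. Of 8 MGE and Shh response genes 3 fell (4 adjusted over the list alone; adjusted p = 0.0385), Nkx2-1 at −0.44 ± 0.04 and Nkx6-2 (uncertain) at −1.27 ± 0.21. Cells of low Nkx2-1 clusters made up more of the Gsx2+Ascl1+ class (53.3% against 37.7%), and within those clusters Nkx2-1 stood at −0.10 and Lhx6 at 0.59, neither past the threshold. Those clusters were chosen for low Nkx2-1 (8.18 to 19.8 CPM), so they cannot show whether the difference holds where these genes are expressed. In the other progenitor clusters, of the 76 named genes tested, no gene past the threshold here changed sign. Of 12 radial glia genes 5 rose (8 adjusted over the list alone), Slc1a3 at 0.49 ± 0.06 and Ptprz1 at 0.27 ± 0.03. Of the Notch ligands and modulators 2 of 9 rose (3 adjusted over the list alone), Dll1 (uncertain) at 0.53 ± 0.05 and Hes6 at 0.32 ± 0.03, and of the receptors and effectors 3 of 9, Hes5 at 0.23 ± 0.03 and Notch1 at 0.23 ± 0.04. The camera calls of these 3 lists were lost (adjusted p = 0.0816 for each with an estimated correlation). Of 52 G2 and M phase genes 5 rose (11 adjusted over the list alone; adjusted p = 0.445), Cdca8 by 0.12 ± 0.03, and of 42 S phase genes 1 rose and 2 fell (1 and 3 adjusted over the list alone; adjusted p = 0.327). Of 8 stress genes 2 fell (5 adjusted over the list alone; adjusted p = 0.0790), Fos at −0.35 ± 0.06.

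LGE transcription factors split, 3 higher and 5 lower of 15 (4 and 5 adjusted over the list alone; median 0.0077, mean −0.017, no camera call): Dlx2 at 0.24 ± 0.03 against Bcl11b at −0.32 ± 0.04 and Sp9 (uncertain) at −0.29 ± 0.03. The order turned in VZ cells alone (3 rose and 0 fell), in VZ cells of low Nkx2-1 clusters (2 and 0), unthinned (4 and 3) and with the UMI minimum multiplied by 2 (4 and 1). Id genes gave 1 higher (Id2, 0.66 ± 0.11) and 1 lower (Id4, uncertain, −0.26 ± 0.05; 2 lower adjusted over the list alone), with a median of −0.14 and a mean of 0.030 and no camera call. Of 9 cell cycle exit genes 1 rose (Btg2, 0.42 ± 0.04; 2 higher and 1 lower adjusted over the list alone), with the camera test pointing up, without a call, against a median of −0.0028. Of 5 bHLH partners and Olig genes 1 rose, Olig2 at 0.21 ± 0.04, without a camera call, and Gsx1 did not pass. Of 7 dorsal LGE and pallial boundary genes 1 rose and 1 fell (2 and 1 adjusted over the list alone; median 0.12, mean −0.32, no camera call). The one that fell was Neurog2, the proneural factor of the pallium, at 0.647 and 0.90 CPM in Gsx2+Ascl1+ against 12.04 and 6.26 CPM in Gsx2-Ascl1+ cells. It was also the 1 of 4 pallial lineage genes that fell (2 adjusted over the list alone; adjusted p = 0.0816). None of 4 vascular, blood and immune genes passed. Without the replicate block edgeR called 0 genes (357 at an unadjusted p under 0.05), and DESeq2 with the block called 138. In VZ cells alone 247 genes passed, Tubb3 turned to 0.24 (adjusted p = 5.0e-05 in edgeR) and 1 neuronal differentiation gene rose and 0 fell.

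The third class comparison sets Gsx2 without Ascl1 against neither. Gsx2+Ascl1- cells had more Ntrk2 (0.88 ± 0.09, adjusted p = 9.82e-11, both replicates), the ephrin receptor gene Epha5 (0.78 ± 0.06), Lix1 (0.68 ± 0.06) and Pax6 (0.47 ± 0.08), and less Nkx2-1 (−0.52 ± 0.07), Lhx6 (−0.83 ± 0.22), Stmn2 (−0.72 ± 0.09) and the growth factor gene Fgf15 (uncertain, −1.17 ± 0.15). In all 138 genes were higher and 76 lower, 214 of 12161.

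Of 12 radial glia genes 6 rose (9 adjusted over the list alone; adjusted p = 0.0553 with an estimated correlation, where the camera call was lost), Ptprz1 at 0.43 ± 0.03 and Slc1a3 at 0.38 ± 0.07. Of 9 Notch receptors and effectors 4 rose (adjusted p = 0.0586, lost), Hey1 at 0.57 ± 0.11 and Hes5 at 0.22 ± 0.03, and of 9 ligands and modulators Dll1 alone (uncertain, 0.89 ± 0.20) with no camera call. Unthinned, 0 ligands rose and 3 fell, and with the UMI minimum multiplied by 2, 0 rose and 1 fell. Of 12 neuronal differentiation genes 5 fell (6 adjusted over the list alone; adjusted p = 0.0363, held), Gad2 at −0.82 ± 0.18. Of 8 MGE and Shh response genes 4 fell (7 adjusted over the list alone; adjusted p = 0.0363, held), Nkx6-2 (uncertain) at −1.34 ± 0.19 and Hhip at −2.30 ± 0.56, beside low Nkx2-1 cluster shares of 64.9% and 50.2%. Of 52 G2 and M phase genes 12 rose (24 adjusted over the list alone; adjusted p = 0.131, lost), Cdk1 at 0.33 ± 0.05 and Cenpf at 0.27 ± 0.04, while 0 of 42 S phase genes passed in edgeR and the camera test for S phase pointed down (adjusted p = 0.0598, lost). Of 8 stress genes 2 fell, Fosb at −0.94 ± 0.25 and Fos at −0.33 ± 0.09 (adjusted p = 0.131, lost). With another seed 1 stress gene passed, and it rose. The sign of Fosb turned with a mitochondrial maximum of 5%. That of Slc1a3 turned in the progenitor clusters other than low Nkx2-1, and that of Gad2 in VZ cells of low Nkx2-1 clusters. Of 15 LGE transcription factors 1 rose and 2 fell (1 and 3 adjusted over the list alone; adjusted p = 0.131, lost). That order turned in VZ cells alone (3 rose and 0 fell), in VZ cells of low Nkx2-1 clusters (2 and 0) and in the other clusters (2 and 0). Id genes gave 1 lower (1 higher and 1 lower adjusted over the list alone; 1 rose and 0 fell unthinned, with doublets kept and with another seed), bHLH partners and Olig 1 higher (adjusted p = 0.160, lost), and cell cycle exit genes no call (median 0.096, mean −0.11). Gsx1 and the vascular, blood and immune genes did not pass the threshold. Dorsal LGE and pallial boundary genes gave 1 higher and 1 lower (1 and 2 adjusted over the list alone, no camera call), the lower one again Neurog2, at 1.30 and 0.473 against 12.53 and 8.76 CPM and also the 1 pallial lineage gene that fell (2 adjusted over the list alone; adjusted p = 0.131, lost). Without the replicate block 0 genes passed in edgeR (477 at an unadjusted p under 0.05), and DESeq2 with the block called 114. With cluster as covariate 10 genes passed of the 7947 tested.

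The last class comparison sets the single-positive classes against each other. Gsx2-Ascl1+ cells had more Gadd45g (2.71 ± 0.27, adjusted p = 0.00823, both replicates), Dll3 (2.32 ± 0.26), Lhx6 (2.13 ± 0.18), Insm1 (2.00 ± 0.10) and Tubb3 (1.38 ± 0.04), and Gsx2+Ascl1- cells more Ppp1r1a (−2.33 ± 0.11), Fabp7 (−2.01 ± 0.07), Slc1a3 (−1.92 ± 0.07), Pax6 (−1.30 ± 0.09) and Hes1. In all 1233 genes were higher and 1183 lower in Gsx2-Ascl1+ cells, 2416 of 12161, and 543 without the replicate block. With cluster as covariate 175 passed, 63 higher and 112 lower.

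All 12 radial glia genes fell and 9 of 15 LGE transcription factors rose, Dlx5 at 1.93 ± 0.11 and Dlx6 at 2.20 ± 0.17, and 10 of 12 neuronal differentiation genes rose and 1 fell (adjusted p = 0.0119 for each list with an estimated correlation). VZ and SVZ naming markers are among these genes, and SVZ cells were 49.4% of Gsx2-Ascl1+ and 9.50% of Gsx2+Ascl1- cells. Of 9 Notch ligands and modulators 5 rose and 1 fell (adjusted p = 0.0350), of 9 receptors and effectors 1 rose and 7 fell (adjusted p = 0.0197), and all 4 Id genes fell (adjusted p = 0.0241). The calls of the remaining lists were lost or absent: 6 of 9 cell cycle exit genes rose (adjusted p = 0.0719), 40 of 52 G2 and M phase genes (47 adjusted over the list alone; adjusted p = 0.201), 15 of 42 S phase genes with 1 lower (adjusted p = 0.177), 4 of 5 bHLH partners and Olig genes (1 lower adjusted over the list alone; adjusted p = 0.177), Gsx1 (adjusted p = 0.177) and 2 of 8 MGE and Shh response genes (adjusted p = 0.0625), with Nkx2-1 at 1.30 ± 0.06. Stress genes gave 2 higher and 1 lower (median 0.16, mean 0.094, the camera test pointing down without a call), dorsal LGE and pallial boundary genes 2 higher and 3 lower (median 0.055, test pointing down without a call) and vascular, blood and immune genes 1 lower, Pdgfrb. The 2 of 4 pallial lineage genes that rose (no camera call) were Neurog2, at 12.04 and 6.26 against 1.30 and 0.473 CPM, and Eomes, at 2.36 and 0.764 CPM against no UMI. In VZ cells alone 792 genes passed, and there 6 of 52 G2 and M phase genes fell and 0 rose. Bhlh partners and Olig genes turned in the progenitor clusters other than low Nkx2-1 (0 rose and 2 fell). Stress genes turned without the replicate block, in VZ cells alone and in those other clusters (0 rose and 1 fell in each). MGE genes turned with cluster as covariate (0 rose and 1 fell). Cells of low Nkx2-1 clusters made up 37.7% of Gsx2-Ascl1+ and 64.9% of Gsx2+Ascl1- cells.

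Phase calls, which also read the depth and RNA content of a cell, put 63.3% ± 0.472 of Gsx2+Ascl1+ cells in G2/M and 28.9% ± 0.317 in S (n = 2). The shares were 54.3% ± 3.94 and 36.4% ± 0.808 in Gsx2+Ascl1- cells, 59.5% ± 0.460 and 31.6% ± 0.342 in Gsx2-Ascl1+ cells, and 45.9% ± 3.27 and 42.7% ± 3.12 in Gsx2-Ascl1- cells. Among VZ cells alone the G2/M shares were 58.6% ± 0.880, 55.8% ± 2.36, 52.0% ± 0.691 and 46.8% ± 3.23 in the same order. No cycling is read from these calls alone.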

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

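The split of progenitor clusters by Nkx2-1 and the test of the difference between its 2 parts were chosen after the data had been seen, as were the clusters named here.

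Clusters c4, c9 and c22 stayed unnamed and entered no comparison, yet had signal above the highest level in the endothelial-like, microglia-like or erythroid-like cells (6.72 CPM for Ascl1, 3.02 for Gsx2 and 0.707 for Gsx1). In c22 this held for Ascl1 alone. Ascl1 stood at 749 ± 78.0 CPM (SD, n = 2) in c9, which was led by Cdkn1c, Gsx1, Rgs16, Gadd45g and Isl1, a factor of striatal and cholinergic neurons, at 321 ± 4.76 CPM in c4, led by Fgf17, Fgf15 and Otx2, and at 39.8 ± 4.84 CPM in c22. Gsx1 stood at 118 ± 13.7 CPM in c9 and 3.78 ± 1.26 CPM in c4, and Gsx2 at 28.1 ± 12.9 CPM in c9 and 19.2 ± 5.11 CPM in c4. Both c9 and c4 also carried the MGE and preoptic factor Nkx2-1, at 707 and 282 CPM over both replicates. Lhx8 stood at 349 CPM in c9, so its markers do not place this cluster in the LGE.

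The log2 fold change of Gsx2+Ascl1+ over Gsx2+Ascl1- cells differed between low Nkx2-1 clusters and the other progenitor clusters for 181 of 11619 genes by an interaction term in edgeR, of which 136 were larger in low Nkx2-1 clusters and 68 had opposite signs in the 2 parts. Of 79 named genes 25 differed. It was larger in low Nkx2-1 clusters by 3.09 for Helt (4.40 against 1.32), 2.71 for Dll3 (4.07 against 1.36), 1.98 for Mfng (2.66 against 0.68), 1.15 for Hes6 (2.44 against 1.29) and 1.29 for Dll1 (uncertain, antisense overlap; 3.01 against 1.72). Among differentiation genes the difference was 1.93 for Insm1 (3.18 against 1.255), 2.22 for Myt1 (2.88 against 0.66), 0.88 for Tubb3 (1.49 against 0.61), 0.52 for Elavl3 (1.06 against 0.54), 1.15 for Elavl4 (1.65 against 0.50) and 2.56 for Gad2 (2.72 against 0.16). For LGE transcription factors it was 2.63 for Dlx6 (3.51 against 0.88), 0.64 for Dlx2 (1.83 against 1.19), 0.98 for Bcl11b (1.43 against 0.44) and, with antisense overlap, 1.43 for Dlx1 (2.61 against 1.18) and 1.82 for Sp9 (2.63 against 0.81). It was 1.19 for Olig2 (1.18 against −0.016), 0.31 for Nasp (0.28 against −0.034) and 2.74 for Rgs16 (uncertain; 3.74 against 1.00).

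Differences with a negative sign were −0.77 for Fabp7 (−1.80 against −1.03), −0.71 for Ptprz1 (−1.06 against −0.35) and −0.66 for Hes1 (−1.25 against −0.58), which were further below 0 in low Nkx2-1 clusters. The mitotic genes Top2a (difference −0.46; 0.37 against 0.83), Tpx2 (−0.55; 0.22 against 0.77) and Cenpe (−0.54; 0.46 against 1.00) had smaller folds there. The stage mix of the classes also differed between the 2 parts. In low Nkx2-1 clusters VZ cells were 216 of 411 and 321 of 677 Gsx2+Ascl1+ cells in replicates 1 and 2. They were 166 of 171 and 193 of 206 Gsx2+Ascl1- cells there. In the other clusters the SVZ cluster c8 alone gave 10 of 83 and 25 of 124 Gsx2+Ascl1- cells. No explanation of the differences in fold, such as this mix, was tested.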

How the results depend on the processing

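The settings that split progenitors by Nkx2-1, and the counts of list members under each setting, were chosen after the data had been seen. Below, the first comparison is Gsx2+Ascl1+ against Gsx2+Ascl1-, the second Gsx2+Ascl1+ against Gsx2-Ascl1+, the double-negative one Gsx2+Ascl1- against Gsx2-Ascl1- and the last Gsx2-Ascl1+ against Gsx2+Ascl1-. Except where stated, the cause of a change was not tested. The first comparison had 2049 genes past the threshold. Of these, folds taken in replicate 2 alone and in replicate 1 alone had the same sign for 2047 and 2043. These genes had passed in a fit of both replicates, so most of this agreement follows from how they were chosen. Folds from 1 replicate leave no residual degrees of freedom, so they give no counts. The odds ratio ranged from 1.77 to 2.06 and the progenitor share from 52.7% to 53.3% with 1 replicate left out. Depth limits detection, so that a negative cell is one without a UMI at 6200.

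Same-numbered classes deviated together (correlations of 0.458 to 0.788 over 6 pairs of classes), because they are cells of the same library. Without the replicate block the 4 counts were 284, 0, 0 and 543 in the order above (edgeR; 357 and 477 genes had an unadjusted p under 0.05 in the second and double-negative comparisons, and DESeq2 with the block called 138 and 114). Without it 1 MGE gene passed in the first comparison and 1 stress gene in the last (each 0 rose and 1 fell), and 3 stress genes from SVZ to neurons (2 rose and 1 fell).

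DESeq2's Wald test gave counts of 1305, 138, 114 and 1529. Without thinning, which leaves more UMIs per cell, counts were 3708, 1265, 657 and 3822, and thinned to 3100 UMIs they were 779, 129, 83 and 1228. With cluster as covariate they were 250, 59, 10 and 175 over fewer tested genes (7947), and within low Nkx2-1 clusters with that covariate 161, 32, 13 and 156. Small sums were left out of both fits. Of the SVZ sums of Gsx2+Ascl1- cells, only those of c8 entered the fit over all progenitor clusters. None entered the fit within low Nkx2-1 clusters. For comparisons with that class, both fits thus rest mainly on VZ clusters. In VZ cells alone the counts of the first, second and last comparisons were 586, 247 and 792. In VZ cells of low Nkx2-1 clusters they were 246, 47, 59 and 267, and in the other progenitor clusters 472, 216, 52 and 596. Low Nkx2-1 clusters gave 138 in the second and 102 in the double-negative one, the UMI minimum multiplied by 2 gave 239 and 85, and a mitochondrial maximum of 5% gave 180 and 81. Resolution 0.5 gave 121 in the double-negative one. The progenitor share was 52.5% with the higher UMI minimum, 48.8% with the mitochondrial maximum of 5%, 46.9% without doublet removal and 40.1% at resolution 0.5. Of 78 shares of single classes under the alternatives 37 moved by more than the SD between replicates. The 78 include shares with 1 replicate left out, which with 2 replicates cannot move by more than that SD. All 37 thus come from the other alternatives. In replicates 1 and 2, GABAergic neuron-like cells were 0% and 0% at resolution 0.5 and with the higher UMI minimum, and 6.43% and 7.09% without doublet removal. MGE-derived neuron-like cells were 22.4% and 22.4% at resolution 0.5, 4.76% and 9.02% with the mitochondrial maximum of 5% and 10.6% and 6.29% with the higher UMI minimum. Striatal projection neuron-like cells were 15.6% and 17.4% at resolution 0.5, 12.3% and 13.6% with the higher UMI minimum and 3.64% and 7.87% with the mitochondrial maximum of 5%. Unnamed cells ranged from 13.4% to 26.0% over these 4 alternatives. Erythroid-like cells of replicate 2 were 0.595% with the higher UMI minimum, 0.338% without doublet removal and 0.0514% with the mitochondrial maximum of 5%. With the higher UMI minimum pallial progenitor-like cells were 0.416% and 0.409% and pericyte-like cells 0.378% and 0.459%. The odds ratio of co-detection was 2.19 in low Nkx2-1 clusters stratified by cluster.

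Single genes changed sign as follows (log2 fold change). In VZ cells alone: Cdkn2d −0.24, Hes5 0.13 and Sp8 −0.67 in the first comparison; Bcl11b 0.048, Gm13889 0.12, Lhx6 0.22, Rprm 0.26, Rtn1 0.021, Slc32a1 0.83, Sp9 0.018 and Tubb3 0.24 in the second. There Sp9 was at 0.050 and Tubb3 at 0.17 in the double-negative one, and Btg1 at −0.064, Cdkn2d −0.36, Cenpe −0.016, Cenpf −0.068, Hes5 0.033, Tcf4 −0.13 and Top2a −0.11 in the last. With cluster as covariate the first had Bcl11b −0.019, Cdkn2d −0.17, Emx2 0.057, Gad2 −0.29, Hes5 0.021, Lhx6 −0.16 and Sp8 −0.56, and the last Cdkn2d −0.14, Emx2 0.14 and Tcf4 −0.054.

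VZ cells of low Nkx2-1 clusters had Btg1 −0.015, Cdkn2d −0.34, Top2a −0.067 and Tpx2 −0.011 in the first comparison, and Gm13889 0.18, Lhx6 0.80, Ptprz1 −0.015, Rprm 0.17, Rtn1 0.040, Sp9 0.13, Stmn2 0.028, Tubb3 0.22 and Usp1 −0.013 in the second. The double-negative comparison had Gad2 0.10, Sp9 0.14 and Tubb3 0.024, and the last Anp32e −0.0027, Btg1 −0.0052, Cdkn2d −0.39, Cenpe −0.015, Cenpf −0.14, Emx2 0.17, Tcf12 −0.0037, Tcf4 −0.064 and Top2a −0.17. The other progenitor clusters had Egr1 −0.047, Nasp −0.042, Olig2 −0.021, Pax6 0.097 and Sp8 −1.04 in the first, Slc1a3 −0.14, Sp9 0.13 and Tubb3 0.0026 in the double-negative one, and Dlk1 −0.026, Nasp −0.029 and Olig2 −0.43 in the last. Low Nkx2-1 clusters with cluster as covariate had Btg1 −0.13, Cdkn2d −0.23, Emx2 0.013, Gad2 −0.34 and Sp9 −0.048 in the first and Rprm 0.22 in the second. The last had Anp32e −0.021, Btg1 −0.063, Cdkn2d −0.28, Emx2 0.21, Gad2 −0.11, Stmn2 −0.37, Tcf12 −0.0077, Tcf4 −0.0079 and Top2a −0.012. Low Nkx2-1 clusters without it had Lhx6 0.59 and Rprm 0.28 in the second, Tcf4 −0.097 in the last, Olig1 0.62 and Olig2 0.32 from VZ to SVZ, and Fos 0.12 from SVZ to neurons.

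With the UMI minimum multiplied by 2, Hey1 was at −0.055 and Rprm at 0.045 in the second, Cenpf at −0.15 in the last, and Aurka at −0.034, Cenpa at −0.21 and Tpx2 at −0.068 from VZ to SVZ. A mitochondrial maximum of 5% gave Rprm 0.19 in the second and Fosb 0.26 in the double-negative one. Thinned to 3100 UMIs, Aurka was at −0.065 in the second, and unthinned, Dlx2 at −0.067 in the double-negative one.

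List members past the threshold turned in majority as follows. In VZ cells alone 3 LGE transcription factors (3 rose) and 1 neuronal gene (1 rose) passed in the second comparison, 3 LGE transcription factors in the double-negative one (3 rose), and 6 G2 and M phase genes (6 fell) and 1 stress gene (1 fell) in the last. In VZ cells of low Nkx2-1 clusters 1 G2 and M phase gene and 1 MGE gene passed in the first (each fell), 2 LGE transcription factors in the second and 2 in the double-negative one (all rose), and 4 G2 and M phase genes (4 fell) and 3 dorsal genes (2 rose and 1 fell) in the last. With cluster as covariate 1 MGE gene passed in the first and 1 in the last (each fell), and within low Nkx2-1 clusters 1 dorsal gene in the last (1 rose). The other clusters gave 2 LGE transcription factors in the double-negative one (2 rose) and 2 bHLH partners and Olig genes (2 fell) and 1 stress gene (1 fell) in the last.

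Unthinned, 7 LGE transcription factors passed in the second (4 rose and 3 fell), and 3 Notch ligands (3 fell) and 1 Id gene (1 rose) in the double-negative one. The UMI minimum multiplied by 2 gave 6 MGE genes in the first (2 rose and 4 fell), 5 LGE transcription factors in the second (4 rose and 1 fell), 1 Notch ligand in the double-negative one (1 fell), and from VZ to SVZ 28 S phase genes (19 rose and 9 fell) and 28 G2 and M phase genes (9 rose and 19 fell). A mitochondrial maximum of 5% gave 28 S phase genes (24 rose and 4 fell) and 3 bHLH partners and Olig genes (1 rose and 2 fell) from VZ to SVZ. Low Nkx2-1 clusters gave 30 S phase genes there (26 rose and 4 fell) and 3 stress genes from SVZ to neurons (2 rose and 1 fell), as did resolution 0.5 for the latter (3). In the double-negative comparison, another seed gave 1 Id gene and 1 stress gene (each rose), and keeping doublets 1 Id gene (1 rose).

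Leaving out the folds from 1 replicate, there were 1318, 1314, 1298 and 1321 values of named genes under the alternatives in the 4 comparisons. Of these, 1077, 915, 894 and 1099 had the same direction and the same side of the threshold. From VZ to SVZ 303 of 315 did, and from SVZ to neurons 304 of 315. Of the 124 readout genes past the threshold from VZ to SVZ, 86 kept their sign and 20 passed with the opposite sign with the UMI minimum multiplied by 2. With a mitochondrial maximum of 5% 113 and 3 did, and in low Nkx2-1 clusters 112 and 7 of the 123 tested.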

Other observations

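The stratified odds ratio, the Notch ligand test with control genes and both tests of the MGE genes were chosen after the result was seen, and the tests of doublets, cell quality, cluster mix by shuffling and the number of genes with control genes were set before. A further prediction on VZ cells alone was set aside in favour of the shuffles within clusters, and the values in VZ cells stand above.

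Ascl1 was high in 1 cluster of MGE-derived neuron-like cells. In c13, led by the interneuron genes Sst, Npy and Nxph1, Ascl1 stood at 239 ± 44.3 CPM (SD, n = 2) and Gsx2 at 8.79 ± 4.17 CPM. Other genes that differed between the libraries were the embryonic globin gene Hbb-y, at 3344 CPM in replicate 1 and 179 CPM in replicate 2, Gm42418, at 5273 and 1172 CPM, and Rps26-ps1, at 81.5 and 243 CPM.

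The 2049 genes that differed between Gsx2+Ascl1+ and Gsx2+Ascl1- cells could in part follow the mix of clusters in the classes. Shuffling class labels within each cluster and library gave 1170.3 genes on average (1034 to 1327 in 20 shuffles), 57.1% of the real count, which argues against cluster mix as the whole cause but leaves it a large part. The number of genes is not specific to Ascl1: of 40 control genes detected in about as many cells, drawn from the 200 nearest, 3 split Gsx2+ cells with as many genes (median 223.5, highest 2587). The Notch ligand and modulator list is different: 0 of 40 control genes gave a median as high as 0.758 (highest 0.187), though shuffles within clusters gave 0.410 on average and 0.669 at most, so the mix of clusters is a large part here too; this was a test split off after the control counts and the real median, but not the control medians, were known. No biological explanation was tested for any of these patterns, and a cause shared by Ascl1 and the ligand genes stays open.

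Co-detection of Gsx2 and Ascl1 could come from doublets, from cell quality or from the mix of clusters. Among cells with a low doublet score the log2 odds ratio was 1.02 and 1.14 times that of all cells, which argues against doublets that the score can find. The top-scoring cells had been removed before. Doublets of 2 progenitor-like cells may score low, so the test cannot exclude them. Of 200 control genes detected in as many cells as Ascl1, 0 and 2 had an odds ratio with Gsx2 as high in replicates 1 and 2, which argues against a rise in the detection of all genes together. Stratified by cluster the log2 odds ratio was 1.15 and 1.16 times the unstratified one, which argues against the mix of these clusters. Co-expression in the same progenitors may remain as a hypothesis, found and tested in the same cells.

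The lower MGE and Shh response genes of Gsx2+Ascl1+ than of Gsx2-Ascl1+ cells may follow the smaller share of high Nkx2-1 clusters among them. Shuffling labels within cluster and library gave a median of −0.32 on average (−0.58 to 0.00036 in 20 shuffles) against −0.71, which argues against cluster mix as the whole cause. Within low Nkx2-1 clusters the median was 0.0098 over genes that went both ways near the detection floor, a value seen first and judged not to decide. With 40 control genes in place of Ascl1 the median ran from −1.11 to −0.50 over all 40, and 26 gave one as low as −0.71. Over the 40 splits 301 to 633 genes passed (462 for Ascl1), so neither is specific to Ascl1. Position within clusters, and so the place of cells along the eminence, stays open.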
